A study of Mus musculus with 50 samples.

How the data were processed

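Total RNA-seq of 50 libraries was used, from brain, heart, liver, lung and stomach of 3 Tnrc18 BAH-domain mutant and 2 wild-type mice with 2 duplicate libraries per mouse. The deposited files were 5 tables, 1 per organ, whose signal values the authors made by dividing the gene counts of each library by 1 size factor, with each organ normalized apart. This was read from the values: every value was a whole multiple of 1 step per library within a tolerance of 0.001 of a step, in 100% of values, and the median ratio to the geometric mean was alike in the 10 libraries of each table. Per the submitters' processing notes, reads were handled on mm10 with STAR 2.4.2, Salmon 1.4.0, Picard 2.22.4, FastQC 0.11.9 and DESeq2 1.38.2, with no role or order given. The lists of genes differed between organs, so the authors had removed low genes by a rule that is not stated. Repeats were processed apart by the authors and were not analysed here.

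Groups were taken per the labels. The mouse was the replicate, so the 2 libraries of a mouse were averaged and 3 mutant mice were compared with 2 wild-type mice in each organ. Because the tables held normalized values, the test was the one set for that case before the data were examined: limma 3.58.1 in R 4.3.3, with eBayes, a trend and robust settings, on log2 of the value plus a pseudocount of 1, for genes above 1 in at least 2 of the 5 mice. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, and adjusted p are limma values unless camera or another test is named. Whole reads were recovered by dividing by the step, and edgeR 4.0.16 (quasi-likelihood, TMM), DESeq2 1.42.0 and limma-voom were run on them as alternatives. The choice between normalized values and recovered reads as the lead test was a judgement, and both counts are given.

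Gene lists and cell type markers, 70 in all and 22 of them for every organ, were fixed before the data were examined. A list was tested where at least 3 members were measured, by camera with a preset correlation of 0.01, again by camera with an estimated correlation, and by fry, with adjustment over the lists of an organ. Members were counted over all genes and adjusted over the list alone. Genes were named by a rule fixed in advance: the 10 largest rises and 10 largest falls among called genes with all mutant mice on 1 side of both wild-type mice and a mean log2 CPM of at least 0, the 3 smallest p in a direction with too few calls, Tnrc18, up to 4 members of each list described by smallest p, 10 genes called in the most organs, and 5 each for the interaction and averaged tests. Some genes named by this rule are not reported here. Where all libraries of a group had 0 reads, the fold was computed against a floor of 3 reads over that group and given as a lower bound. Such floors and intervals cover counting error only.

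The effect of genotype was compared between organs by a limma interaction test on 25 mouse-by-organ values, and averaged over the organs of each mouse before a limma test on 5 mice. The interaction test used a common spread per gene over all organs and had no term for the mouse. Organs with the same mouse number were taken to come from 1 mouse, and the averaged test, like the list tests, used log2 of the normalized values in place of log2 CPM. Overlap of calls was tested by a one-sided Fisher exact test. Pairs of libraries were compared by the median over genes with at least 20 reads of the squared difference from a common proportion, scaled to 1 under binomial noise. Wild type was averaged to 1 sample as an alternative chosen after seeing the data. The rule for it was that the highest index across the wild-type mice be at most 1.1 times the highest within them, and that pairing the libraries by label not give the smallest sum of indices. A looser form without the second condition added liver. The edgeR test with TMM had been set beforehand as the lead test for tables that held counts. Its use on recovered reads as an alternative was decided after seeing the data. Further alternatives chosen after seeing the data were leaving out 7 libraries that stood apart, and removing from each mouse the trend (loess, span 0.5) with transcript length and GC content. Gene lengths, GC content and classes came from the reference annotation and covered at least 96.7% of tested genes in each organ.

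The tests were run on simulated data with 100 genes changed by each fold. With 2 wild-type mice, 4-fold changes were recovered for 86% of genes in brain, 96% in heart, 99% in liver, 74% in lung and 90% in stomach, and 2-fold changes for 37%, 70%, 60%, 6% and 25%. The unchanged genes among those called numbered 16 of 139, 16 of 182, 20 of 179, 16 of 96 and 7 of 122, which is above the nominal share of 5% in each case. With wild type counted as 1 sample 4-fold changes were recovered for 73%, 88%, 91%, 31% and 75%. The simulated wild type was there still the mean of 2 mice drawn apart, so the case of 4 libraries from 1 sample was not simulated. For the interaction, 95 of 100 genes changed 4-fold in lung alone and 18 of 100 changed 2-fold were recovered, with 19 unchanged among 132 called. For the averaged test all 100 of each were, with 22 unchanged among 273 called. The organs of a mouse were drawn independently there. A mouse effect shared by its organs was therefore not simulated, and this recovery can be too high. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.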

Results

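Total RNA was sequenced from brain, heart, liver, lung and stomach of adult mice that carried 2 homozygous substitutions, W2745A and Y2747A, in the BAH domain of Tnrc18, and of wild-type littermates. TNRC18 is a chromatin protein that the series title describes as a reader of H3K9me3, a histone mark of silenced chromatin, with a part in the silencing of endogenous retroviruses. The question was what the substitutions in this reader domain did to gene expression in each organ. Each organ was represented by 3 mutant and 2 wild-type mice with 2 duplicate libraries per mouse, which gave 10 libraries per organ and 50 in all. The tables held genes but no repeat families, so transposable elements were not analysed here. The number of genes listed was 15056 in brain, 13279 in heart, 11814 in liver, 15396 in lung and 12998 in stomach. Reads recovered per library ranged from about 3516700 to 7214600 in brain, 3295600 to 6283200 in heart, 4235400 to 5645400 in liver, 2445200 to 6233300 in lung and 1553300 to 6117900 in stomach. Levels below are normalized read counts, given as mean ± SD over mice, and changes are log2 fold changes of mutant over wild type.

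Before mutants were compared with wild type, the libraries of each organ were compared in pairs by an index that is 1 when 2 libraries differ by counting noise alone. In lung the libraries of the 2 wild-type mice differed by 1.13 to 1.30, whereas the duplicates within those mice differed by 1.21 and 1.25. Libraries of different mutant lungs differed by 4.08 to 25.4. The upper end came from duplicate 1 of mutant mouse 2, which differed from its own duplicate by 14.6. Without that library the range was 4.08 to 11.99. In heart, pairs across the wild-type mice ranged from 1.26 to 6.29 and pairs within them from 1.22 to 6.65. In stomach the same ranges were 1.34 to 7.36 and 2.97 to 7.24. In these 3 organs the wild-type libraries of different mice were thus at most 1.1 times as far apart, by the highest index, as duplicates of 1 mouse, and wild-type levels are given there as 1 mean without SD. A single library of wild-type mouse 2 set both highest values in heart (duplicate 2) and in stomach (duplicate 1). Without it, pairs across the mice were at 1.26 and 1.30 in heart and 1.34 and 2.59 in stomach. Duplicates of wild-type mouse 1 were at 1.22 in heart and 2.97 in stomach. In brain the 2 wild-type mice stood apart, at 4.43 to 8.60 against 1.49 to 3.14 within a mouse. Liver lay between, at 1.36 to 2.06 across and 1.24 to 1.91 within the mice, and whether its wild type counts as 1 sample or 2 depends on which of 2 forms of the rule is used. The rule was set after the data were seen, so the number of genes called in each organ is followed by the number with the 4 wild-type libraries averaged to 1 sample, which leaves 3 mutant mice against 1 wild-type value.

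**Figure D1:**
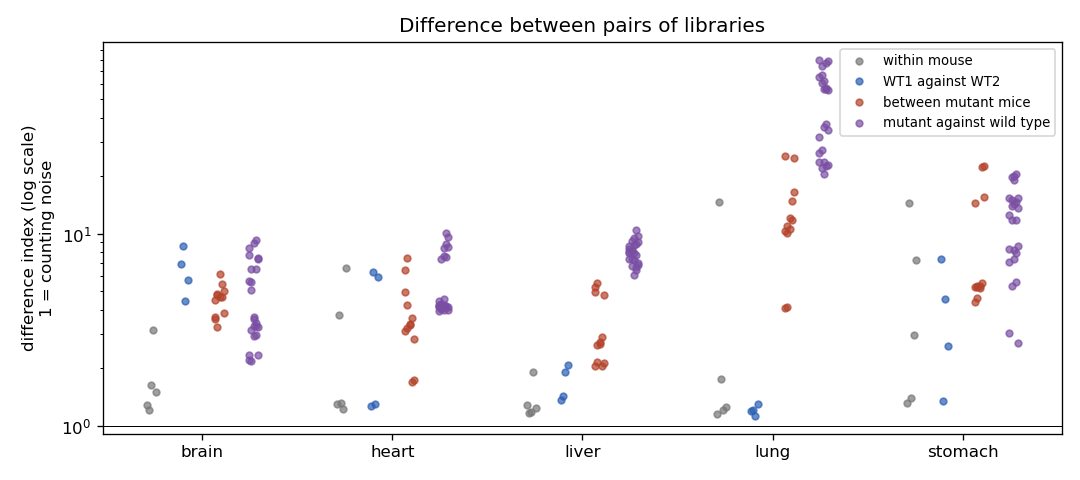
Difference index of pairs of libraries within each organ, on a log axis where 1 is counting noise. Each point is 1 pair, colored as duplicates within a mouse, WT1 against WT2, different mutant mice, or mutant against wild type. In lung the WT1 and WT2 pairs reach at most 1.30, while pairs of different mutant mice start at 4.08.

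Tnrc18 mRNA, from the mutated gene itself (ENSMUSG00000039477.16, mm10 chromosome 5, 142724661 to 142817662, minus strand), was detected in every organ and passed the test in none. In brain it stood at 1145 ± 83.9 in mutants (SD, n = 3) and 1282 ± 70.1 in wild type (SD, n = 2), a log2 change of -0.16 (limma adjusted p = 0.993). The largest differences were in lung, with 279 ± 163 in mutants against 794 in wild type and a log2 change of -1.69 (adjusted p = 0.0515), and in stomach, with 104 ± 49.7 against 223 and a log2 change of -1.18 (adjusted p = 0.405). In heart the levels were 321 ± 103 and 417, a log2 change of -0.42 (adjusted p = 0.421). In liver they were 58.2 ± 18.98 and 32.5 ± 3.41, a log2 change of 0.77 (adjusted p = 0.113). The 3 mutant lungs differed widely, at 262, 451 and 126, and the lung change passed the test at -2.12 without mutant mouse 2 and at -1.21 without mutant mouse 3. The liver change passed at 1.02 without mutant mouse 1 and the stomach change at -1.54 without mutant mouse 2. When the trend of each mouse with transcript length and GC content was removed, the change shrank to -0.28 in lung and -0.41 in stomach, turned to 0.0115 in brain and 0.0519 in heart, and passed the test at 0.80 in liver.

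In liver, the genes of fatty acid synthesis were lower in mutants as a group. Of 17 lipogenesis genes 14 fell and none rose, and 17 fell when adjusted over the list alone. Fasn, which encodes fatty acid synthase, was at 2447 ± 363 in mutants (SD, n = 3) against 21361 ± 963 in wild type (SD, n = 2), a log2 change of -3.14 (adjusted p = 1.59e-05). Acaca, the acetyl-CoA carboxylase that supplies its substrate, changed by -2.14, the elongase Elovl6 by -2.67 and the lipogenic regulator Thrsp by -2.35. The list had a median log2 change of -1.78 and a camera adjusted p of 2.17e-19, against an adjusted p of 0.0598 with an estimated correlation. Of its members 7 still fell with wild type counted as 1 sample. Of 22 cholesterol synthesis genes 6 fell and none rose, or 8 when adjusted over the list alone, with changes of -1.32 for Mvd, -1.12 for Fdps and -0.79 for Sqle. The camera adjusted p of this list was 0.00950, and its adjusted p was 0.660 with an estimated correlation, and no member passed with wild type counted as 1 sample.

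**Figure D2:**
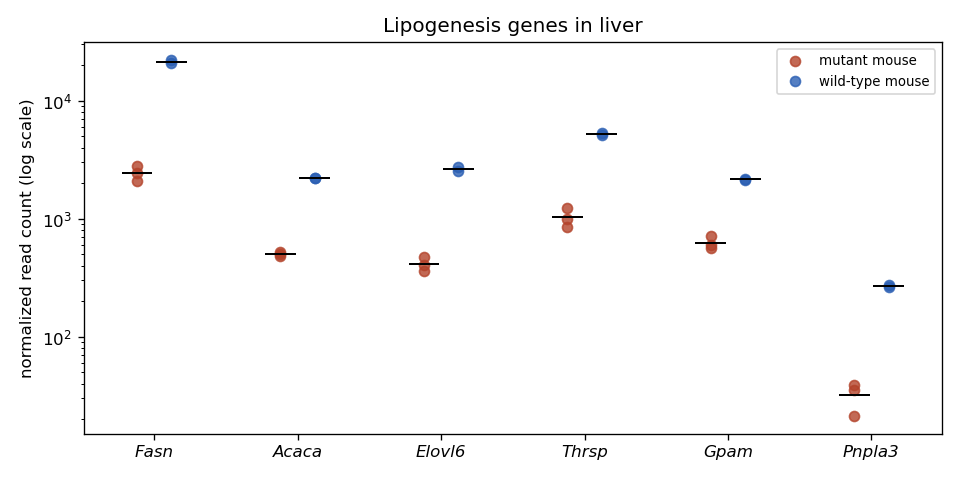
Normalized read counts, on a log axis, of the 6 lipogenesis genes with the smallest p in liver. Each point is the mean of the 2 libraries of 1 mouse, and each line is the mean of the 3 mutant or 2 wild-type mice. All mutant points lie below the wild-type points, with Fasn at 2447 on average in mutants and 21361 in wild type.

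Several genes that are higher in female than in male mouse liver were among those with the largest falls. Of 23 such genes 10 fell and 1 rose, and adjusted over the list alone 10 fell and 5 rose. The list had 7 positive members and a median change of -0.53, or -0.16 with edgeR. The sulfotransferase gene Sult2a1 was at 5.51 ± 0.914 in mutants and 995 ± 10.4 in wild type, a log2 change of -7.27 (adjusted p = 7.52e-07). Sult2a2 fell by 6.53. Among cytochrome P450 genes the log2 change was -9.96 for Cyp3a41b, -8.10 for Cyp3a16, -6.27 for Cyp3a41a and -4.08 for Cyp3a44. The camera adjusted p was 0.00109 and the adjusted p was 0.660 with an estimated correlation, while 6 members fell with wild type counted as 1 sample. Mup19, a major urinary protein gene, had no reads in mutants and was at 194 ± 45.8 in wild type, which makes it at least 446-fold lower. Several of these genes have near-identical copies, so reads cannot be assigned to single members with certainty. Of 17 genes that are higher in male liver, 5 rose and 1 fell, or 6 and 1 when adjusted over the list alone, without a call for the list (camera adjusted p = 0.152). They included the protease inhibitor gene Serpina1e, which rose by 3.50 from 107 ± 1.75 to 1252 ± 332. The sex-linked genes, 5 of which were tested in each organ, were called as a list in none and had no member past the test.

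Other liver groups were higher in mutants. Of 16 immediate-early genes 4 rose and 1 fell, and adjusted over the list alone 5 rose and 1 fell. The transcription factor gene Egr1 rose by 3.88, from 11.97 ± 3.66 to 189 ± 36.3 (adjusted p = 5.5e-05), Btg2 by 1.86, Ier2 by 1.66 and Junb by 0.95, with a camera adjusted p of 0.00112 and an adjusted p of 0.660 with an estimated correlation. Of 21 acute-phase genes 5 rose, or 11 with 1 fall when adjusted over the list alone, including the serum amyloid gene Saa2 by 1.13, the fibrinogen chain Fgg by 0.80, the heme carrier Hpx by 0.69 and Itih3 by 0.59 (camera adjusted p = 0.00109, adjusted p = 0.660 with an estimated correlation). Of 16 markers of stellate, biliary and sinusoidal cells 4 rose, such as Col1a1 by 1.05, Lyve1 by 1.30 and Clec4g by 0.61, and 1, Clec4f, fell by 0.70. Over that list alone 5 rose and 1 fell, the camera adjusted p was 0.00224 and the adjusted p was 0.634 with an estimated correlation. Of 22 proliferation genes 2 rose, Stmn1 by 2.51 and Cdk1 by 1.80, or 3 with 1 fall over the list alone (camera adjusted p = 0.00230, adjusted p = 0.768 with an estimated correlation). Of 262 zinc finger genes named Zfp, a family that holds many repressors of retroelements, 11 rose and 2 fell and none passed over the list alone. Their median change was 0.19, and Zfp719 rose by 0.98, Zfp953 by 0.90, Zfp869 by 0.82 and Zfp729b by 0.68 (camera adjusted p = 0.00493, adjusted p = 0.660 with an estimated correlation).

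Small structured RNAs were lower in mutant liver. All 9 snoRNA genes tested fell, with a median log2 change of -4.79, and 6 of them fell with wild type counted as 1 sample. Scarna6 fell by 6.17, from 574 ± 70.4 to 6.97 ± 0.856, and Gm25395 fell by 6.42. The U3 genes Rnu3b3 and Rnu3b4, which have near-identical copies, were also lower, Rnu3b3 with a log2 change of -6.27 and Rnu3b4 at least 251-fold. Along with them went the share of reads from Rn7s, the RNA of the signal recognition particle, which took 29.7% to 31.5% of wild-type and 8.97% to 13.3% of mutant liver libraries. Rpph1, the RNA of ribonuclease P, took 2.38% to 3.25% and 0.145% to 0.188%, so both shares moved with the liver gene lists above. The other genes with the largest rises were Gm12744, at least 18.2-fold, Hapln1 by 3.25, the imprinted transcript H19 by 3.00, the chemokine gene Cxcl1 by 2.76, Cib3 by 2.73, Gm28901, at least 5.87-fold, and Atp6v0e2 by 2.53.

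In the liver test 843 of 11802 genes passed, of which 330 rose and 513 fell. Counting wild type as 1 sample left 42, all among the 843, of which 5 rose and 37 fell, with 1464 genes at an unadjusted p under 0.05, and without wild-type mouse 1 or 2 the counts were 38 and 43. An edgeR test of the recovered reads called 742, with 735 shared. Without mutant mouse 1, 2 or 3 the count was 2940, 1738 and 126. Mutant mouse 3 resembled a mix of the other 2, and if it was one, the liver SD and calls would rest on 2 mutant mice and the count of 126 would apply. Among list members, 2 immediate-early genes and 1 male-biased gene rose with wild type counted as 1 sample, and no acute-phase, stellate, proliferation or Zfp gene passed in that way. Of 29 lists 8 were called by camera, also with wild type counted as 1 sample, or 13 without mutant mouse 1, and none was called with an estimated correlation.

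In lung, ribosomal protein genes, hemoglobin genes and immune cell markers were higher in mutants, and genes of ciliated, vascular and perivascular cells were lower. Of 76 cytosolic ribosomal protein genes 60 rose and none fell, or 70 when adjusted over the list alone, with a median log2 change of 1.77. After removal of the trend of each mouse with transcript length and GC content the median was 0.79 and 36 passed. Rps9 rose by 2.71, from 953 in wild type to 6569.7 ± 2630.1 in mutants (SD, n = 3), Rpl37a by 2.38, Rps21 by 2.32 and Rpl18 by 1.91, each with an adjusted p of 0.0171. The list had a camera adjusted p of 3.59e-21 and an adjusted p of 0.663 with an estimated correlation, a value that all 17 lists called in lung shared. Of 7 erythroid markers 5 rose, or 6 over the list alone, among them the hemoglobin genes Hbb-bs by 2.78 and Hbb-bt by 2.65, which rose from 1761 to 11228 ± 2497, Hba-a2 by 1.76 and Hba-a1 by 1.34, which are near-identical copies (camera adjusted p = 0.00272), and their median change of 1.34 shrank to 0.28 with that trend removed.

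Markers of lymphocytes and myeloid cells moved in the same direction. Of 22 T and NK cell markers 6 rose, also 6 over the list alone, including the T cell receptor component Cd3d by 3.68, Trbc1 by 3.47, Trbc2 by 3.24 and the kinase Lck by 2.90 (camera adjusted p = 9.32e-05). Of 18 B and plasma cell markers 8 rose, or 11 over the list alone, with Jchain up by 3.71 (668 ± 679 in mutants and 35.7 in wild type), Mzb1 by 2.87 and Ighg2c by 2.37 (camera adjusted p = 0.000824). Of 20 myeloid markers 5 rose and 1 fell, or 7 and 1 over the list alone, with S100a9 up by 2.35, Tyrobp by 2.24, Lyz2 by 2.08 and Cd14 by 1.11 (camera adjusted p = 0.00897). Of 28 proliferation genes 8 rose, or 12 over the list alone, such as Ccnb1 by 3.28, Hmgb2 by 2.15, Birc5 by 1.69 and Stmn1 by 1.66 (camera adjusted p = 1.21e-05). Of 14 adipocyte markers 6 rose, also 6 over the list alone, including Cfd by 3.21, Retn by 2.85, Adipoq by 2.57 and Pck1 by 1.82 (camera adjusted p = 0.00564). Skeletal muscle markers had a median change of 2.67 over 14 genes, or 4.54 with edgeR, of which only Pvalb passed, by 3.13, and none over the list alone (camera adjusted p = 0.00541). Tnni2 in that list was at 294 ± 362 in mutants, so the mice differed widely.

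Defense and stress genes were also higher in mutant lung. Of 45 interferon-stimulated genes 5 rose and 1 fell, or 3 and none over the list alone, with Isg15 up from 13.1 to 82.3 on average, Ifi27 up by 1.92, Bst2 by 1.55 and Ifi35 by 1.15 (camera adjusted p = 0.00366). Of 21 genes of MHC class I antigen presentation 4 rose, or 6 over the list alone, Psmb9 by 2.27, H2-M3 by 2.09, Psme2 by 2.07 and Psmb10 by 1.47 (camera adjusted p = 0.0154). Of 15 genes of alveolar macrophages and lung inflammation 2 rose, Cxcl1 by 2.56 and the cytokine gene Il1b by 2.31, the same number over the list alone (camera adjusted p = 0.0129). Of 26 heat-shock and unfolded-protein-response genes 4 rose and none over the list alone, Hspe1 by 2.24, Sdf2l1 by 2.07, Manf by 1.39 and Creld2 by 0.70 (camera adjusted p = 0.0445). The median change of that list was 0.30 and turned to -0.01 with the length and GC trend removed.

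Genes of cilia, clustered protocadherins and vessels were lower in mutant lung. Of 13 ciliated cell markers 5 fell and 1 rose, or 6 and 1 over the list alone, with the dynein heavy chain genes Dnah9 at -2.58 and Dnah5 at -2.36, Cfap43 at -1.61 and the single rise in Tppp3, by 1.39 (camera adjusted p = 0.0179). Hydin, Dnah10 and Dnah6, which also encode parts of cilia and were among the genes with the largest falls, changed by -3.19, -3.05 and -2.90. Of 33 clustered protocadherin genes 15 fell and none rose, or 24 over the list alone, with Pcdhga12 at -1.83, Pcdhgb4 at -1.65, Pcdhga7 at -1.61 and Pcdhgc3 at -1.53 (camera adjusted p = 3.68e-07), with reads partly shared among copies. Of 10 pericyte and smooth muscle markers 5 fell, or 8 with 1 rise over the list alone, with Notch3 at -1.89, Pdgfrb at -1.65, Cspg4 at -1.44 and Myh11 at -1.35 (camera adjusted p = 0.00541). Of 12 lung endothelium markers 3 fell, with Cdh5 at -1.52, Kdr at -0.95 and Ednrb at -0.78, or 7 with 1 rise over the list alone (camera adjusted p = 0.0393). Of 20 circadian clock genes 4 fell and 1 rose, or 8 and 1 over the list alone, with Per1 at -1.42, Cry2 at -1.15, Arntl at -1.07 and Clock at -0.82 (camera adjusted p = 0.0239). Markers of alveolar type 2 cells had no common direction. Of 13 such markers the surfactant gene Sftpc rose by 1.71 and S100g by 1.77, while Abca3 fell by 1.51 and Etv5 fell by 1.13, with 2 rising and 3 falling over the list alone (camera adjusted p = 0.615).

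Genes with short transcripts tended to be higher and those with long ones lower in mutant lung. Across 13401 protein-coding genes the change followed the length of the longest transcript with a Spearman correlation of -0.57, where genes are not independent replicates, and the median log2 change went from 0.995 in the fifth of genes with the shortest transcripts to -0.70 in the fifth with the longest. In the other organs this correlation lay between -0.26 and 0.12. With GC content the correlation was -0.435 in stomach, -0.303 in brain, -0.178 in heart and -0.0413 in liver, against -0.139 in lung. All 12 snoRNA genes rose, with a median of 3.23, and 2 of them rose with wild type counted as 1 sample. Rnu3b3 and Rnu3b1 had no reads in wild-type lung and were at least 1487-fold and 1491-fold higher in mutants, bounds that are uncertain because these genes have near-identical copies, of which Rnu3b4 did have wild-type reads. The share of reads from Rn7s was 14.0% to 16.2% in wild type and 32.8% to 45.3% in mutants. Malat1, a long nuclear RNA, took 1.27% to 1.32% in wild type and 0.108% to 0.338% in mutants, so both shares moved with the ribosomal, immune and ciliary gene groups. With the length and GC trend removed, the median change of protocadherins went from -1.40 to -0.92, of circadian genes from -0.81 to -0.33, of interferon-stimulated genes from 0.65 to 0.36 and of ciliated cell markers from -0.98 to -1.17. B and plasma cell markers went from 1.85 to 1.04, T and NK cell markers from 1.43 to 0.999 and myeloid markers from 1.06 to 0.67. Of these 3 lists 2, 4 and 2 members then passed. Other genes with large rises were Gm9817 by 6.26, Gm23971 by 5.87, the histone gene Hist1h1a by 5.04, Serpinb12 by 4.98, Rn18s-rs5 by 4.97, Asprv1 by 4.74 and Rnu3b4 by 4.29. In some of these the mutant mice differed widely. In mutant mice 1, 2 and 3, Rn18s-rs5 was at 6595, 161530 and 22514, Serpinb12 at 9.01, 38.2 and 232, and Asprv1 at 9.44, 74.5 and 279. Gm23971 had no reads in wild-type mouse 1 and stood at 36.8 in wild-type mouse 2, and its rise was 4.26 with edgeR. Gm13304 was at least 66.1-fold higher. The falls of the same rank were -3.48 for E030026E10Rik, -3.29 for 2700078F05Rik, -3.29 for Erich3, -3.11 for Gm43281, -3.04 for Ccdc187, -3.01 for Egfros and -2.90 for Pclo.

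**Figure D3:**
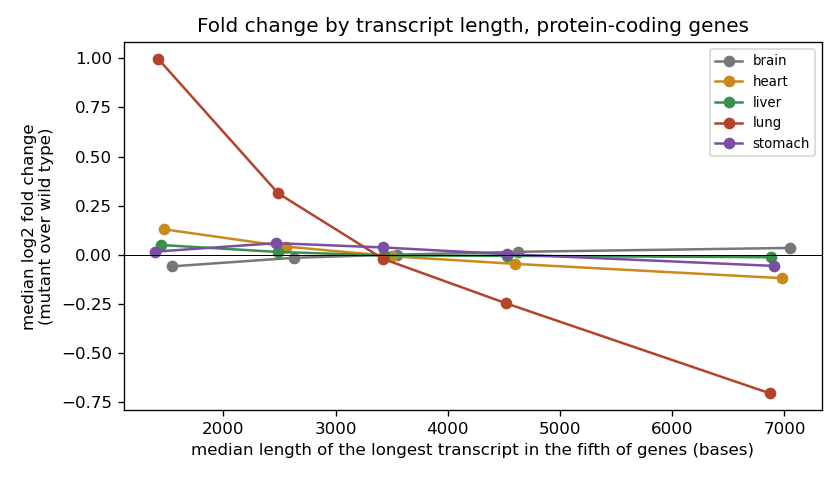
Median log2 fold change of mutant over wild type (y axis) in 5 groups of protein-coding genes ordered by the length of the longest transcript, placed at the median length in bases (x axis). Each line is 1 organ. The lung line falls from 0.995 to -0.70, while in heart it falls from 0.13 to -0.12.

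In the lung test 3534 of 15387 genes passed, 1937 higher and 1597 lower. Counting wild type as 1 sample left 3, all higher and all among the 3534, with 2997 genes at an unadjusted p under 0.05 and a change in Hydin of -3.19 in either fit, and without wild-type mouse 1 or 2 the counts were 4 and 5, so the number rests on treating the near-identical wild-type mice as 2. No member of the 29 lists tested in lung passed in that way. An edgeR test called 4022 genes, 3508 of them shared. Without mutant mouse 1 the count was 1471. Of 29 lists 17 were called by camera, none with an estimated correlation and 16 with wild type counted as 1 sample, where the heat-shock and endothelium lists were lost and immediate-early genes gained.

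In heart, immediate-early genes and genes of fibroblasts and atrial muscle were lower in mutants, and genes of ventricular muscle were higher. Of 24 immediate-early genes 4 fell and none rose, or 15 when adjusted over the list alone. The nuclear receptor gene Nr4a1 fell by 2.02, from 465 in wild type to 118 ± 38.8 in mutants (SD, n = 3), and the changes were -2.10 for Fosb, -1.46 for Atf3 and -1.24 for Fosl2 (camera adjusted p = 8.91e-10, adjusted p = 0.128 with an estimated correlation). Of 14 fibroblast and matrix genes the collagen gene Col3a1 fell by 0.90, from 2370.3 to 1272 ± 223, or 7 fell over the list alone, with Col1a2 at -0.92, Pdgfra at -0.60 and Fn1 at -0.55 not past the test over all genes (camera adjusted p = 2.12e-07, adjusted p = 0.128 with an estimated correlation). Of 11 atrial markers all had negative changes, with a median of -3.76, or -2.41 with edgeR, but only Tbx5 passed, at -1.18, or 2 over the list alone (camera adjusted p = 9.56e-09, adjusted p = 0.354 with an estimated correlation). Sbk2 in that list was at 49.2 ± 36.3 in mutants and 265 in wild type. Of 12 ventricular markers the myosin light chain genes Myl2 and Myl3 rose by 0.76 and 0.75, or 4 over the list alone, with Kcnj2 at 0.44 and Pln at 0.54 (camera adjusted p = 0.00163, adjusted p = 0.354 with an estimated correlation).

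Further heart lists were called by camera with few single genes past the test. Of 17 fatty acid oxidation genes 14 had positive changes and none passed over all genes, though 4 rose over the list alone, with Acadm at 0.48, Fabp3 at 0.56, Ppargc1a at 0.44 and Hadhb at 0.42 (camera adjusted p = 0.000261, adjusted p = 0.172 with an estimated correlation). Of 11 cardiac stress and fetal genes the natriuretic peptide gene Nppb rose by 0.82, or 2 over the list alone, and Myh7 was at 0.60 (camera adjusted p = 0.0155, adjusted p = 0.289 with an estimated correlation). The median of that list was 0.43 but its mean was -0.07, since members went both ways. Ribosomal protein genes were positive in 75 of 76 cases with a median of 0.21 and none past either test (camera adjusted p = 9.56e-09, adjusted p = 0.530 with an estimated correlation). All 8 erythroid markers were positive, with a median of 0.76 and none past either test (camera adjusted p = 0.00278, adjusted p = 0.530 with an estimated correlation). Of 33 clustered protocadherins Pcdhgc3 fell by 0.69, also the 1 fall over the list alone (camera adjusted p = 0.000411, adjusted p = 0.172 with an estimated correlation). Lists called lower with no member past the test over all genes were myeloid markers, with a median of -0.27 over 18 genes and 1 fall over the list alone (camera adjusted p = 0.00224, adjusted p = 0.182 with an estimated correlation), and adipocyte markers, with a median of -2.22 over 13 genes, or -0.71 with edgeR, and none over the list alone (camera adjusted p = 0.00371, adjusted p = 0.556 with an estimated correlation). The same held for MHC class I genes, with a median of -0.27 over 21 genes (camera adjusted p = 0.00352, adjusted p = 0.530 with an estimated correlation), and imprinted genes, with a median of -0.17 over 30 genes (camera adjusted p = 0.0350, adjusted p = 0.530 with an estimated correlation), neither with a member past the test over the list alone.

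Single heart genes among those with the largest rises were Cpxm2 by 1.75, Ahrr and Gnb3, each by 1.63, Plekhh1 and the water channel gene Aqp8, each by 1.59, Cnksr1 by 1.34, Myot by 1.21 and Gm15441 by 1.19, and Klhl34 rose from 17.4 to 47.8 ± 6.77. Among those with the largest falls, Gm23849 and RP23-325D10.3 had no reads in mutants and were at least 123-fold and 33.9-fold lower. The adenylate cyclase gene Adcy1 fell by 2.52, from 130.1 to 22.4 ± 6.12, and the changes were -3.25 for the chemokine gene Cxcl13, -2.48 for Npy1r, -2.37 for Gprin3, -2.28 for Slc7a7 and -2.14 for Cntfr. In the heart test 121 of 13270 genes passed, 37 higher and 84 lower. With wild type counted as 1 sample limma called 0, with 812 genes at an unadjusted p under 0.05, and DESeq2 with the 2 wild-type mice called 336. An edgeR test called 60, of which 57 were shared and 12 rose and 48 fell, and with the trend in transcript length and GC content removed 138 rose and 79 fell. Without mutant mouse 1, 2 or 3 the count was 1282, 187 and 22, and it was 1 without either wild-type mouse. Duplicate 2 of wild-type mouse 2 differed from its own duplicate by an index of 6.65 and duplicate 2 of mutant mouse 2 by 3.77, and the count was 352 without these 2 libraries, 358 with duplicate 1 of each mouse alone and 7 with duplicate 2 alone. Of 26 lists 13 were called by camera, the same number with wild type counted as 1 sample and none with an estimated correlation.

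In stomach 2 genes passed, both higher in mutants. Gm14288, a predicted gene, had no reads in wild type and was at 19.4 ± 1.43 in mutants (SD, n = 3), at least 21.8-fold higher (adjusted p = 0.0137). Lyg1, a lysozyme-like gene, was at 62.1 ± 11.2 against 14.9, a log2 change of 1.97 (adjusted p = 0.0391). No gene fell, and those nearest to it were Gm20458 at -1.22, RP24-78M9.7 at -3.50 and the snoRNA Snora73a at -1.24, with adjusted p of 0.160, 0.201 and 0.255.

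Of the stomach lists, 19 markers of forestomach squamous epithelium had a median change of 0.48, with none past the test over all genes and 4 over the list alone, and with Sprr3 at 1.65, Krtdap at 1.54, Krt10 at 0.99 and Sprr1a at 0.91 (camera adjusted p = 0.00227). The 11 parietal cell markers had a median of 0.45, with the proton pump subunit gene Atp4b at 0.81 and Atp4a at 0.47 (camera adjusted p = 0.0174). The 29 proliferation genes had a median of 0.30, with Ccnb2 at 1.28, Top2a at 0.55 and Pcna at 0.49 (camera adjusted p = 0.00612), and neither list had a member past the test over the list alone. The 11 skeletal muscle markers were lower, with a median of -1.56, or -0.99 with edgeR, 1 fall over the list alone, and Ryr1 at -2.58 and Ckm at -1.04 (camera adjusted p = 1.8e-05). For each of these 4 lists the adjusted p was 0.963 with an estimated correlation. The libraries also differed in their RNA classes along with genotype, and list changes were not tested apart from that. Malat1 took 0.0236% to 0.0540% of reads in wild-type and 0.0622% to 0.140% in mutant stomach, and Rn7s took 39.1% to 46.0% and 23.6% to 34.7%, apart from 51.1% in duplicate 1 of mutant mouse 2. Duplicate 1 of wild-type mouse 2 stood apart, with about 1553300 reads, 21.2% ribosomal RNA-like reads and 1019 genes at 0, and without both of these libraries 17 genes passed. Of the 12983 genes tested 1273 had an unadjusted p under 0.05. With wild type counted as 1 sample limma called 1 gene, not one of the pair, with 368 at an unadjusted p under 0.05. The edgeR test called 0, with 1099 at an unadjusted p under 0.05, DESeq2 called 78 and limma-voom 0. Without mutant mouse 1, 2 or 3 the count was 4, 132 and 53, and without wild-type mouse 1 it was 5. The number of lists called was 9 without mutant mouse 1, 8 without mutant mouse 3 and 2 without either wild-type mouse.

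In brain no gene passed. The closest was the U3 gene Rnu3b3, which had no reads in mutants and 86.7 ± 56.0 in wild type (SD, n = 2), at least 184-fold lower (adjusted p = 0.204). Markers of choroid plexus and cerebellum were lower in mutants as lists by camera with its preset correlation, and neither list was called with an estimated one (adjusted p = 0.977 for both). All 12 choroid plexus markers had negative changes, with a median of -1.26, including Kl at -1.48, Sostdc1 at -1.29, Folr1 at -1.23 and Enpp2 at -0.97 (camera adjusted p = 2.56e-08). All 12 cerebellum markers were negative, with a median of -1.46, and the granule cell gene Gabra6 was at 0.518 ± 0.451 in mutants and 101 ± 138 in wild type, so the 2 wild-type mice were far apart (camera adjusted p = 2.34e-07). Cbln3 was at -3.95, Cbln1 at -1.75 and Neurod1 at -1.33. Wild-type mouse 1 also stood apart in RNA classes, with Rn7s at 13.2% and 9.20% of reads against 4.26% to 8.80% in the other brain libraries. The list changes were not tested apart from that.

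The 10 striatal neuron markers were all positive, with a median of 0.80, Drd1 at 1.54, Adora2a at 1.24 and Rgs9 at 1.02 (camera adjusted p = 0.0121, or 0.198 with wild type counted as 1 sample). Of 9 hypothalamus and pituitary markers 6 were negative and 3 positive, with a median of -0.24, and Oxt was at -2.69, Hcrt at -2.81 and Avp at -1.16, with 1 fall over the list alone (camera adjusted p = 0.0392). The 7 erythroid markers had a median of -0.69 (camera adjusted p = 0.00190). The 337 Zfp genes had a median of 0.09 and the 55 clustered protocadherins of 0.07, each with a camera adjusted p of 0.0121. None of the other 6 lists had a member past the test over the list alone, and the adjusted p was 0.977 with an estimated correlation for each of the 7 called of 31 lists, a number that became 14 without mutant mouse 3. Single genes nearest to a rise were the imprinted gene Snurf, at 39.5 ± 3.83 against 13.6 ± 4.04, Plac9a, at least 15.4-fold higher, and Net1 at 0.66, and those nearest to a fall were RP23-325D10.3 at -3.68 and Wnt7a at -0.89, each with an adjusted p of 0.993. Of the 15021 genes tested by limma 204 had an unadjusted p under 0.05, against 175 with wild type counted as 1 sample and 206 by edgeR, both also with 0 calls, and DESeq2 called 1.

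Factors of H3K9me3 and retroelement silencing, the group nearest to the mutated protein, showed few changes. In liver 3 of 26 fell and none rose, also 3 over the list alone, with changes of -0.90 for Zfp809, a repressor of retroviruses, -0.68 for 2810474O19Rik and -0.63 for the demethylase gene Kdm1a, while the corepressor gene Trim28 was at -0.51 (adjusted p = 0.0809). In lung 1 rose and 2 fell of 28, and over the list alone 2 fell. In brain, heart and stomach none passed either test, nor did any in liver or lung with wild type counted as 1 sample. The list was called in no organ, with camera adjusted p of 0.201 in liver, 0.759 in lung, 0.437 in brain, 0.738 in heart and 0.882 in stomach.

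Across organs the difference between mutant and wild type was not alike for 3053 of 10110 genes by a limma test of the interaction. The genes with the smallest p were small RNAs that fell in liver and rose in lung, such as Gm25395 at -6.42 and 2.45, Scarna6 at -6.17 and 2.47, Scarna10 at -3.91 and 2.49 and Snora73a at -4.21 and 2.73, with 1500011K16Rik at -1.81 and 2.73. Lung alone differed from the mean of the other organs for 4159 genes and liver for 654, against 57 for stomach, 7 for heart and 0 for brain, where 1120 genes had an unadjusted p under 0.05. Without lung the interaction count was 143. These counts took wild type as 2 mice and used a common spread per gene over all organs, with no term for the mouse. The median edgeR dispersion was 0.0647 in lung against 0.0195 in liver. The lung count can therefore be too high. The share of reads from Rn7s also moved with genotype, down in liver and up in lung. The mutation and the composition of the libraries therefore cannot be told apart here.

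Genes called lower in heart and in lung overlapped by 24, among them Map1b, Sort1, Fat3 and Pcdhgc3, where 8.29 were expected by chance (Fisher exact test, adjusted p = 9.59e-06 over 10 pairs of organs in each direction). Genes called higher in heart and in liver overlapped by 4 against 0.586 (adjusted p = 0.0252). Liver and lung shared 42 higher genes against 42.2 expected and 29 lower genes against 48.2 (adjusted p = 1 for both, one-sided for more overlap), among the former Stmn1 and the histone gene Hist1h3c. Adcy1 fell in heart and in liver. Hagh and Tcta rose in 3 organs, heart, liver and lung, by 0.67, 0.56 and 1.29 for Hagh and by 0.78, 0.63 and 1.09 for Tcta, and 101 genes were called in 2 organs in 1 direction. Since organs share mice, and the calls in lung and heart fall to 3 and 0 with wild type counted as 1 sample, these overlaps carry the same limit. Heart and lung also had the most negative correlations of the change with transcript length, at -0.257 and -0.572. The overlap of heart and lung was not tested apart from that trend.

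Averaged over the 5 organs of each mouse, no gene passed limma, with 2952 of 10110 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0936. Fasn had an averaged change of -1.35, made up of -3.14 in liver, -2.60 in heart, -0.63 in stomach, -0.30 in lung and -0.09 in brain. The other genes with the smallest p were Gm10335 at 1.48, Fam213b at 0.92, the transcription factor gene Creb3l2 at -0.71 and Gm25395 at -1.04. Without mutant mouse 2 the count was 4826, and an edgeR fit that took all organ values as independent called 2737.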

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

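The splits of the mice into other groups and the tests of single library shares were chosen only after the counts of genes were seen, whereas the interaction test was set before.

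In heart, 3 shares of reads stood apart in 1 library, wild-type mouse 2 duplicate 2. Its Malat1 share was 0.0811% (95% Wilson interval 0.0789 to 0.0834) against 0.113% to 0.119% in the other wild-type heart libraries, its Rpph1 share was 0.664% (0.658 to 0.671) against 0.318% to 0.363%, and its share of ribosomal RNA-like genes was 5.19% (5.17 to 5.21) against 2.31% to 2.43%. In lung, mutant mouse 2 duplicate 1 had a ribosomal RNA-like share of 17.0% (16.94 to 17.01) against 4.80% to 8.93% in the other mutant libraries. In stomach, mutant mouse 2 duplicate 2 had a Malat1 share of 0.140% (0.136 to 0.143) against 0.0622% to 0.0775%, and duplicate 1 of the same mouse had a ribosomal RNA-like share of 12.4% (12.395 to 12.467) against 5.67% to 6.85%. Of 50 tests by Dixon's rule, each of a single measure in the wild-type or mutant libraries of an organ, 6 stood out in this way. Chance gives 2.5 if the values are independent, which duplicates of a mouse and shares of the same library are not.

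The difference between mutant and wild type was not alike across organs for 3053 genes by the interaction test, which took wild type as 2 mice. It also used a common spread per gene over all organs. The smallest adjusted p were 2.49e-09 for Gm25395, 3.68e-09 for Scarna6, 3.01e-08 for Scarna10, 2.00e-07 for 1500011K16Rik and 2.94e-07 for Snora73a, each with a fall in liver and a rise in lung. Without lung the number was 143.

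The 5 mice of an organ can be split into 3 and 2 in 10 ways, too few for a share of splits under 0.05. In liver the true split gave 843 genes and was the 1 split with as many, with at most 6 in the others. In lung it gave 3534 and was again the 1 such split, with at most 24 in the others. The true split alone sets the 2 wild-type mice against all others, so their likeness in lung, and to a lesser degree in liver, favours its count there whatever the cause. In heart 2 of the 10 splits gave at least the true count of 121, and the highest other gave 422. In stomach 4 of the 10 gave at least 2, and the highest other gave 97. In brain the true split gave 0, a count that every split must reach, and the highest other gave 425. The highest other count came from setting mutant mice 2 and 3 against the rest in heart, and mutant mice 1 and 3 in stomach. Both splits kept the wild-type mice together, so they are not free of genotype. In brain it came from mutant mouse 3 with wild-type mouse 1, a split that mixes genotypes. The source of these counts was not tested.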

How the results depend on the processing

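Wild type counted as 1 sample, the fits without doubted libraries and those with the length and GC trend removed were chosen only after the data were seen. Running the edgeR test with TMM as an alternative was also decided then, though it had been set beforehand as the lead test for tables with counts. Of 294 alternatives to the 18 answers 199 kept their direction and side of the threshold or stayed within 1.5 times the count, and of 1393 for the 62 single genes 1090 did, while 303 lost the call and none changed direction. The single genes were chosen as called with all mutant mice on 1 side of both wild-type mice. The alternatives used the same libraries, so a change of direction was unlikely from the start. No cause was tested unless stated. Leaving out each mouse gave 1 to 1282 genes in heart, 38 to 2940 in liver, 4 to 5041 in lung, 2 to 132 in stomach and 0 to 4826 for the averaged effect. The lowest counts in heart, liver and lung came without a wild-type mouse and the highest in all 5 without a mutant mouse, and with 1 wild-type sample left its spread was taken to be that of the mutants. The same left-out mice gave 7 to 14 lists in brain, 8 to 13 in liver and 2 to 9 in stomach. With wild type counted as 1 sample the counts were 0 in heart, 42 in liver, 3 in lung and 1 in stomach.

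By tool, the counts in heart were 60 with edgeR and TMM, 61 with RLE, 336 with DESeq2, 45 with no filter and 54 with a stricter one in edgeR. In stomach they were 0 with TMM, 0 with RLE, 78 with DESeq2, 0 with no filter, 0 with a stricter filter and 0 with limma-voom, and DESeq2 called 1 gene in brain. Taking libraries as separate samples, which counts duplicates as replicates, gave 1278 in heart, 2922 in liver, 8117 in lung and 21 in stomach. Duplicate 1 alone gave 358 in heart, 1947 in lung and 0 in stomach, and duplicate 2 alone gave 7 in heart, 558 in liver and 61 in stomach. A replicate block on the mouse number, which mutants and wild type share for only 2 numbers, gave 24 in heart, 221 in liver, 5457 in lung and 467 in stomach. The limma-voom fit with a duplicate block gave 765 in heart, 1449 in liver, 5385 in lung and 0 in stomach. A log2 change of at least 1 left 71 in heart and 286 in liver, since it adds a condition. A pseudocount of 5 gave 4 in stomach. Without doubted libraries 352 passed in heart and 17 in stomach. With the length and GC trend removed 217 passed in heart and 1299 in liver.

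With an estimated correlation camera called 0 lists in brain, 0 in heart, 0 in liver, 0 in lung and 0 in stomach, and fry, which asks another question, called 0, 5, 2, 3 and 0. The number of genes that differed between organs was 143 without lung. An edgeR fit of the averaged effect that took 25 values as independent called 2737. At an adjusted p under 0.1 the overlaps summed to 470 genes against 107.

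The change in Tnrc18 turned to 0.0115 in brain and 0.0519 in heart with the length and GC trend removed, and shrank to -0.28 in lung and -0.41 in stomach (adjusted p = 0.213 and 0.599). In liver it passed the test at 0.78 with libraries as separate samples and at 0.80 with the trend removed, and ranged from 0.54 to 1.02 with a mouse left out. In lung it passed at -1.51 with DESeq2, -1.53 with a stricter edgeR filter, -1.68 with limma-voom, -1.70 with libraries as separate samples, -1.73 with duplicate 2 alone, -1.21 with the mouse block, -1.71 with the duplicate block and -1.76 without doubted libraries, and ranged from -2.12 to -1.21 with a mouse left out. In stomach it passed at -1.15 with the mouse block and ranged from -1.54 to -0.86 with a mouse left out.

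Across genes, centred levels of mutant and wild-type mice with the same number correlated at -0.08 and 0.33 in brain, 0.12 and 0.30 in heart, 0.17 and 0.18 in stomach and near 0 in liver and lung. The numbers were not read as pairs, since only 2 were shared and the labels do not say what they mark across genotypes. Both correlations in heart and stomach were positive, but they are not separate evidence, since the 2 wild-type mice deviate from their mean by opposite amounts. In heart, duplicate 2 of wild-type mouse 2 had index 3.94 with duplicate 2 of mutant mouse 2 and 6.65 with its own duplicate. In stomach, duplicate 1 of wild-type mouse 2 had index 3.05 with duplicate 1 of mutant mouse 2 and 7.24 with its own duplicate. In simulated lung data 6% of 2-fold changes were recovered.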

Other observations

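The tests of 1 sample sequenced 4 times, of depth, of a mixed sample and of chance among combinations were chosen only after the results were seen, whereas the tests of length bias and of other cell types in lung were set before theirs.

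Further gene lists in liver and lung held single genes past the test without a call for the list. Of 16 liver genes of bile acid synthesis and transport 1 rose and 4 fell, or 3 and 5 when adjusted over the list alone. Nr0b2, a repressor of bile acid synthesis, rose by 2.29, from 17.7 ± 0.558 to 91.1 ± 7.59, and Cyp7a1, the rate-limiting enzyme of that pathway, was at -1.05, the bile salt export pump gene Abcb11 at -0.63 and Baat at -0.62 (camera adjusted p = 0.299, adjusted p = 0.781 with an estimated correlation). Of 76 ribosomal protein genes in liver 11 rose and 9 fell, or 19 and 17 over the list alone, with Rpl13a at -1.73, Rpl17 at -1.54, Rps24 at -0.76 and Rpl21 at 0.95 (camera adjusted p = 0.412). In lung 2 of 26 subunits of the HDAC, SIN3 and NCOR corepressors rose and 5 fell, or 2 and 7 over the list alone, with Sap130 at -1.40, Ncor1 at -1.28 and Rbbp4 at 1.48 (camera adjusted p = 0.386). Of 11 alveolar type 1 markers in lung 1 rose and 3 fell, or 1 and 4 over the list alone, with Col4a3 at -1.74, Rtkn2 at -0.94, Akap5 at -0.92 and Hopx at 1.14 (camera adjusted p = 0.104). With wild type counted as 1 sample no lung gene named here passed.

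Lung changes followed transcript length, with short genes higher and long ones lower in mutants. After the trend with length and GC content was removed from each mouse, 2455 genes passed, and 1703 of the 3534 calls, 48.2%, stayed called in the same direction. Set in advance, a count below 0.1 of the 3534 would have pointed to this trend as the whole cause, which 2455 is far from. More than 0.5 of the calls staying would have argued against it. The trend and genotype therefore cannot be told apart for the calls as a set. The correction took out only the average trend of each mouse, so the 1703 that stayed can still hold a remainder of it. The 67 immune and erythroid markers tested in lung kept a median change of 0.74 after the correction, from 1.34 before, which is consistent with more reads from immune cells in the mutant samples, as with Lyz2 at 41926 against 8825 before the correction, while the erythroid markers alone kept 0.28 of 1.34, between the bounds of 0.25 and 0.5 set for all 67, which leaves blood open. Lung itself holds such cells, and whether they differed by dissection or by genotype was not tested.

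In lung the wild-type libraries may all stem from 1 sample. The highest index between libraries of wild-type mouse 1 and 2 was 1.30, near that of duplicates at 1.21 and 1.25, as this explanation needs. That likeness is also what raised the explanation, so it is no separate test of it. The lowest index between different mutant mice was 4.08, for mutant mice 1 and 2, but the duplicates of mutant mouse 2 differed by 14.6. Mutant mice 1 and 3 had duplicates at 1.15 and 1.75 and differed from each other by 10.6 to 11.99. The difference between mutant mice 1 and 3 argues against too little depth to tell mice apart. Genetically alike littermates with 1 tissue state stay open, as untested.

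In liver, mutant mouse 3 lay between mutant mice 1 and 2. On genes not used to set the weight, a linear mix with a weight of 0.45 for mouse 1 matched it with an index of 1.24 over 5335 genes, against 1.29 for a mix on the log scale, 4.14 for mouse 1 alone and 2.63 for mouse 2 alone. Of 51 genes at least 4-fold apart between mice 1 and 2, 48 were in between in mouse 3. Choosing genes far apart in mice 1 and 2 favours this for any other mouse, so the count does not argue for a mix. By the index a mixed sample is a candidate explanation. It rests on 1 split of the genes, however, and came from a search of 150 combinations. Of these, 2 others, lung mutant mouse 1 as a mix of mutant mouse 3 and either wild-type mouse, lowered the better single index by a factor as large as 2.12 but to 4.22 and 4.09. Chance among combinations and a mouse with an intermediate state therefore stay open, and if it was a mix, the liver SD and the 843 calls would rest on 2 mutant mice, with 126 calls without mouse 3.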
